A study of Capra hircus with 8 samples.

How the data were processed

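Skin of cashmere goats and milk goats was sampled in months 3, 6, 9 and 12, with 1 library per breed and month and 8 libraries in all. Per the labels, total RNA was extracted with TRIzol, polyadenylated RNA was selected and directional paired-end libraries were sequenced. The same protocol text speaks of embryos, while the tissue is given as skin, and the labels do not resolve this. The tool the authors name is Bowtie2, whose role and version are not given in the sources used here. The genome build is not given there either, so no coordinates are printed. The authors deposited 3 tables. The first holds raw read counts per gene, deposited without normalization, for 18815 genes, each with at least 1 read in some library. The second holds FPKM, computed by the authors from the same genes per kilobase and per 1000000 mapped reads. The third holds raw read counts, also deposited without normalization, for another gene set of 20780 genes. The unit of each table was checked on its values: counts were whole numbers, and the ratio of counts to FPKM between libraries differed from its median by at most 0.0151% over 368 genes with at least 50 FPKM in every library. The columns of the 2 count tables were matched by correlating gene profiles over 12073 shared symbols, and each of the 8 columns matched best the column of the same breed and month. One table names the cashmere goats with a transliterated word, which this match assigned to the cashmere columns of the other table.

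The first count table was used throughout. Totals were 7480053 to 8718429 reads in the cashmere goat libraries and 11333734 to 13899750 in the milk goat libraries. The totals and their TMM factors set the smallest detectable level: 3 reads, the limit that a count of 0 allows, stand for 0.231 to 0.395 CPM. PCR reads without molecular identifiers are not independent molecules, so exact binomial (Clopper-Pearson) 95% intervals of reads and floors cover counting error only. Intervals of medians over genes are 95% bootstrap intervals over the genes of a list or set. Intervals of shares of called genes are exact binomial ones. Both kinds treat genes as independent, which they are not, and do not cover the spread between libraries.

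Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on the breed, which left 14085 genes, and libraries were scaled by TMM. Quasi-likelihood F tests were run in a model of month (4 levels) and breed, which leaves 3 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. This fit gave the breed effect, the month effect, month 9 against month 3 and month 12 against month 6. A full breed by month interaction would leave no residual degrees of freedom. The breed by season test was therefore a test of both interaction coefficients in a model of breed and the cosine and sine of a 12-month cycle, with 2 residual degrees of freedom. CPM used TMM factors, and log2 CPM used a prior count of 2. Standard errors of edgeR log2 fold changes were taken from the fold change and its F statistic.

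Gene lists for the hair follicle, the skin, other cell types, general processes and RNA quality were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Lists with at least 5 tested members (29) were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with p-values adjusted over the lists. No list call holds with an estimated correlation. That p is printed beside each call, except on the season axes, where the smallest of each axis is given. The fry test, whose p asks whether the genes of a list move on balance one way, was run beside it. Among the fixed lists, those for mitochondrial genome genes and for sex chromosomes had 0 members in the table and gave no value. Comparisons within 1 month are ratios of 1 library to 1 library without a test, with list medians ranked among 10000 random lists of the same size matched on expression. Shares of reads were compared over the 4 months with an exact paired sign-flip permutation test.

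Genes were named by a rule: a symbol not starting with LOC and, for the breed effect, the 10 higher and 10 lower genes with the largest fold change among those past the threshold, with a mean of at least 5 CPM and the same sign in all 4 months. For month contrasts the rule took 5 genes in each direction past the threshold, and none passed. Within 1 month it took the 5 highest and 5 lowest ratios among genes with at least 100 reads. For lists it took up to 4 members past the threshold, otherwise 2 as values. Other genes were chosen after their values were seen, including the members named for the comparison without month 12. A few genes that the rule takes are not reported here.

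Alternatives were DESeq2 1.42.0, RLE factors, a scaling without hair keratins, no filter and a stricter filter, limma on log2 FPKM with a pseudocount of 1 or 0.1, a model without month, camera with an estimated correlation, and each library left out in turn. Chosen after seeing the data were the second count table, the fits without both month 12 libraries or both month 3 libraries, a gene-length trend, thinning of all libraries to the smallest total, a hair score as a covariate, library totals without TMM factors, hair gene shares scaled by TMM, the ribosomal list without kinases, another form of the season, list tests on the season coefficients and hair classes found by product name. The tests were tried on simulated counts. These used the observed gene means and trended dispersions, with 100 genes each changed by a log2 of 1 or 2. Recovered were 60% and 97% for the breed effect, 30% and 90% for month 9 against month 3 and 24% and 84% for breed by season. The simulated genes were independent and held no departures of single libraries, so these shares do not measure the power in the real libraries.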

Results

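Gene expression was measured by RNA sequencing of polyadenylated RNA in skin of cashmere goats, which grow a fine undercoat, and of milk goats. Each breed was sampled in months 3, 6, 9 and 12, with 1 library per breed and month and 8 libraries in all. The title given to the study concerns the seasonal cycle of the hair follicle, in which a phase of growth (anagen) is followed by regression (catagen) and rest (telogen). The labels list the month as an age while the stated design speaks of months, so whether months of the year or months of life are meant is not settled. The labels also do not say whether a library came from 1 animal or from several, so every p-value of a single gene below measures only the spread between these libraries. List p-values from camera at the preset correlation compare the genes of a list with all other genes, treated as nearly independent. They measure the spread between genes and not the spread between animals. Library totals lay between 7480053 and 8718429 reads in the 4 cashmere goat libraries and between 11333734 and 13899750 reads in the 4 milk goat libraries. Of 18815 genes listed, 14085 were tested. The most abundant gene was TCHH, trichohyalin of the inner root sheath, in 6 libraries, COL1A1, a collagen of the dermis, in milk goats at month 3, and KRT1, an epidermal keratin, in milk goats at month 12. The first principal component held 48.7% of the variance, and the milk goat libraries of months 12 and 3 lay at its low end, at -70.9 and -51.8.

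The first comparison asked which genes differed between the breeds across the 4 months. KAP8 (gene37), a keratin-associated protein of the hair shaft, was 7.02-fold higher in cashmere goats (log2 fold change 2.81 ± 0.50 SE, adjusted p = 0.0356), at 324 ± 354 counts per 1000000 reads (CPM; SD, n = 4) against 42.3 ± 58.0 in milk goats. PPIG (gene1955), a nuclear cyclophilin that binds splicing factors, was 4.12-fold lower in cashmere goats (-2.04 ± 0.22, adjusted p = 0.0218), at 360 ± 114 against 1558 ± 713 CPM. ANKRD12 (gene23156), an ankyrin repeat protein that binds transcriptional coactivators, was 3.50-fold lower (-1.81 ± 0.21, adjusted p = 0.0218), at 747 ± 161 against 2666 ± 872 CPM. NEXN (gene2794), which encodes the actin-binding protein nexilin, was 4.27-fold lower (-2.10 ± 0.26, adjusted p = 0.0243), at 109 ± 10.7 against 504 ± 227 CPM. RPL39 (gene26968), a ribosomal protein gene, was 2.74-fold higher (1.45 ± 0.25, adjusted p = 0.0331), at 122 ± 24.9 against 46.5 ± 18.9 CPM.

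Among the other genes higher in cashmere goats, ETNPPL, which encodes an enzyme that breaks down phosphoethanolamine, differed 6.06-fold (adjusted p = 0.0450), and SHISA2, an inhibitor of Wnt and FGF receptor maturation, 3.34-fold (adjusted p = 0.0461). PDE8B, a cyclic AMP phosphodiesterase, was 3.12-fold higher at 23.7 ± 11.2 against 6.93 ± 0.557 CPM (SD, n = 4; adjusted p = 0.0355). ANXA9, an annexin, CITED4, a transcriptional coactivator, and PPP2R1B, a scaffold subunit of protein phosphatase 2A, were higher by 2.96-fold, 2.95-fold and 2.78-fold. KLK10, a kallikrein protease, and CCNJ, a cyclin, were each 2.73-fold higher. HMGN5, a nucleosome-binding protein, was 4.71-fold lower (adjusted p = 0.0276), at 27.7 ± 11.2 against 151 ± 106 CPM. LSAMP, a neural cell adhesion molecule, was 4.40-fold lower, SCN9A, a sodium channel of sensory neurons, 4.18-fold, and CCDC173 3.89-fold. CELF4, an RNA-binding protein, was 3.78-fold lower and ZC3H6, a zinc finger protein, 3.48-fold. NEFH, the heavy neurofilament subunit, was 11-fold lower (-3.46 ± 0.64, adjusted p = 0.0370), with 79.0 CPM in the milk goat library of month 12 and 0 reads in the cashmere goat libraries of months 6 and 9. Without the cashmere goat library of month 12 NEFH stood at -2.48 (adjusted p = 0.113), and without the milk goat library of that month at -2.50 (adjusted p = 0.145).

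**Figure D1:**
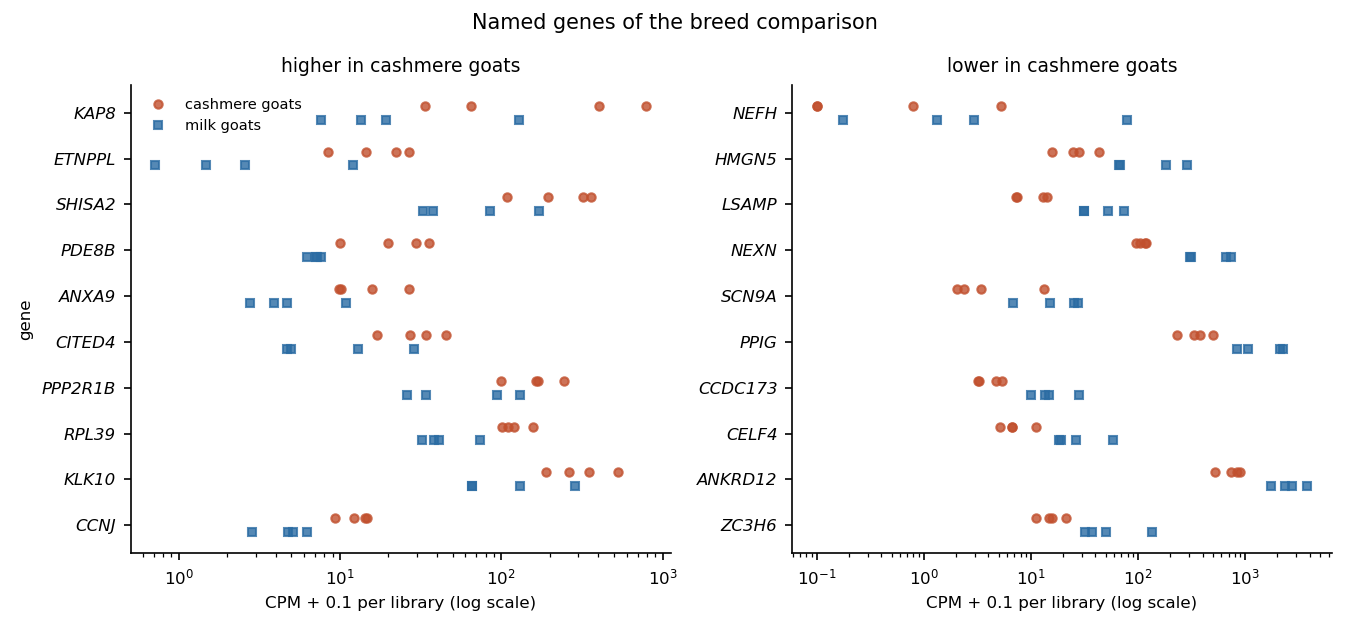
CPM plus 0.1 (log axis) of the 20 genes named by rule in the breed comparison, 1 point per library, with circles for the 4 cashmere goat libraries and squares for the 4 milk goat libraries. The points of PPIG centre on 360 CPM in cashmere goats and 1558 CPM in milk goats, and the highest NEFH point is the milk goat library of month 12 at 79.0 CPM.

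In all, 675 genes passed an adjusted p of 0.05 between the breeds, 207 higher and 468 lower in cashmere goats. Each had the same sign in all 4 months, which is no separate support, since a change of sign would leave a large residual. At an unadjusted p under 0.05 there were 3786 genes, against 704 by chance. The balance of directions moved with the scaling of the libraries: library totals without further factors gave 302 higher and 317 lower, and limma on log2(FPKM + 1) gave 1196 higher and 384 lower. The median of all genes was 0.03 with the scaling used, 0.14 with library totals and 0.16 with FPKM. Small list medians in this comparison are relative to such shifts. Leaving out 1 library leaves its month with 1, which adds no residual, so the 2 runs of a month are not separate checks. The count was 2 without the cashmere goat library of month 3, 4 without that of month 6 and 0 without that of month 9 (3280 at an unadjusted p under 0.05). It was 2, 4 and 2 without the milk goat libraries of months 3, 6 and 9. Without the cashmere goat library of month 12 it was 869 (575 shared with the 675), and without the milk goat library of that month 743 (529 shared).

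Of the lists fixed before the data were examined, 3 of hair-forming cells and 1 of dividing cells were higher in cashmere goats. The 8 hair shaft keratins had a median log2 fold change of 1.44, with 8 of 8 positive (adjusted p = 0.0123; adjusted p = 0.775 with an estimated correlation). None of the 8 passed the test alone, and KRT35 of the hair cortex stood at 1.90 (adjusted p = 0.134). The 10 inner root sheath genes had a median of 1.26 with 8 positive (adjusted p = 0.0285; adjusted p = 0.775 with an estimated correlation), with KRT25 at 1.28 (adjusted p = 0.255) and TCHH at 0.69 (adjusted p = 0.716). The 24 regulators of the hair matrix and cortex had a median of 0.63 with 21 positive (adjusted p = 0.00298; adjusted p = 0.775 with an estimated correlation). The 30 cell division genes had a median of 0.46 with 28 positive (adjusted p = 0.000467; adjusted p = 0.775 with an estimated correlation). In each of these 4 lists, 0 genes passed with edgeR over all genes, and 0 genes passed when adjusted over the list alone. Of 4 keratin-associated proteins, too few for the list test, KAP8 passed, and KRTAP11-1 and KRTAP3-1 stood at 2.78 (adjusted p = 0.0553) and 2.63 (adjusted p = 0.0717). In the second count table, with classes by product name chosen after the data were seen, 27 keratin-associated proteins had a median of 2.61 with 27 positive and 13 called (camera adjusted p = 2.86e-16; adjusted p = 0.268 with an estimated correlation). The 17 shaft keratins of that table had a median of 2.06 with 17 positive and 1 called (adjusted p = 1.05e-06; adjusted p = 0.308 with an estimated correlation). In the first table the list of follicle stem cell and outer root sheath genes stood at -0.14 with 9 of 16 negative (adjusted p = 0.994), and dermal papilla genes at -0.15 with 12 of 21 negative (adjusted p = 0.206). The list calls for hair shaft keratins, inner root sheath genes, matrix regulators and cell division genes in the first table rest on month 12. The 2 runs below, each without 1 library of that month, are nearly the same fit and amount to 1 check. With all libraries the list means were 1.44 for hair shaft keratins, 1.0 for inner root sheath genes, 0.72 for matrix regulators and 0.46 for cell division genes. Without the cashmere goat library of month 12 they were 0.73 (adjusted p = 0.0891), 0.33 (adjusted p = 0.173), 0.34 (adjusted p = 0.0541) and 0.19 (adjusted p = 0.0865) in the same order. Without the milk goat library of that month they were 0.71 (adjusted p = 0.0890), 0.31 (adjusted p = 0.201), 0.32 (adjusted p = 0.0612) and 0.16 (adjusted p = 0.0877).

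Smooth muscle genes were lower in cashmere goats, with a median log2 fold change of -0.47 and 13 of 15 negative (adjusted p = 0.00194; adjusted p = 0.775 with an estimated correlation). DES, the muscle intermediate filament desmin, fell by 1.63 on the log2 scale (adjusted p = 0.0325), LMOD1, an actin nucleator of smooth muscle, by 1.2 (adjusted p = 0.0257), and SYNM, the intermediate filament protein synemin, by 0.78 (adjusted p = 0.0454). Of these 15 genes, 2 higher and 8 lower passed when adjusted over the list alone. This list kept its call without either month 12 library, at adjusted p = 0.00996 and adjusted p = 0.0150. Immediate early genes, which respond to handling and stress of tissue, had a median of 0.38 with 20 of 25 positive (adjusted p = 0.00298; adjusted p = 0.775 with an estimated correlation). DUSP1, a phosphatase of MAP kinases, rose by 0.93, CTGF, a matricellular growth factor, by 0.78, and ZFP36, an mRNA decay factor, by 0.76. With all genes 3 immediate early genes passed, and 6 passed when adjusted over the list alone. The mean of this list was 0.44 with all libraries, 0.27 without the cashmere goat library of month 12 (adjusted p = 0.0835) and 0.25 without the milk goat library (adjusted p = 0.0791).

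Ribosomal proteins, a list taken by symbol prefix, had a median of -0.11 with 54 of 88 negative (adjusted p = 0.0388; adjusted p = 0.897 with an estimated correlation). The prefix also takes 9 S6 kinase genes and RPS19BP1, and without these 10 the median was -0.13 (adjusted p = 0.0143; adjusted p = 0.897 with an estimated correlation). For the 88 the median was 0.01 with library totals and 0.09 with FPKM. Of the 88, 3 were higher and 8 lower over all genes, and 4 higher and 13 lower when adjusted over the list alone. The list mean of -0.14 went to -0.02 without the cashmere goat library of month 12 (adjusted p = 0.693) and to -0.04 without the milk goat library (adjusted p = 0.689), and the list was no longer called. The other 22 of 29 lists were not called. Among their members, ASIP, the agouti signal that turns melanocytes to yellow pigment, was lower (-0.98 ± 0.14, adjusted p = 0.0267). In the dermal papilla list, WIF1, a secreted Wnt inhibitor, was lower by -1.24 (adjusted p = 0.0356) and FGF7, a growth factor for keratinocytes, by -0.66 (adjusted p = 0.0363). The Wnt inhibitor DKK2 (-1.24, adjusted p = 0.0218) and the ligand WNT2 (-1.39, adjusted p = 0.0342) were lower too. The skin surface proteases KLK5 (1.06, adjusted p = 0.0276) and KLK7 (1.38, adjusted p = 0.0379) were higher, as was the fatty acid desaturase gene SCD (1.2, adjusted p = 0.0362).

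The share of reads taken by hair genes was followed in each library. The 8 of 17 listed hair shaft keratins found by symbol in the first count table are a part of the whole. They took 0.0885%, 0.206%, 0.200% and 0.157% of reads in cashmere goats at months 3, 6, 9 and 12. In milk goats they took 0.0259%, 0.143%, 0.183% and 0.00675% (95% exact binomial interval of the last 0.00628 to 0.00724). The cashmere share was thus 23.2-fold that of milk goats at month 12, 3.41-fold at month 3, 1.44-fold at month 6 and 1.09-fold at month 9. The 4 keratin-associated proteins differed 29.97-fold at month 12, 11.5-fold at month 3, 2.77-fold at month 6 and 3.21-fold at month 9. TCHH took 12.96% of reads in milk goats at month 9 and 0.243% at month 12, a 53.3-fold range within that breed, against 2.10% to 6.64% in cashmere goats. Between its highest and lowest month the share of the 8 shaft keratins ranged 2.33-fold in cashmere goats and 27.1-fold in milk goats. In the second count table, 17 shaft keratins found by product name took 1.53%, 2.82%, 3.40% and 2.35% of reads in cashmere goats at months 3, 6, 9 and 12. Their cashmere share was 26.9-fold that of milk goats at month 12, 8.22-fold at month 3, 1.74-fold at month 6 and 1.50-fold at month 9.

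Across the 4 months the log2 difference between breeds was 1.74 ± 1.99 (SD, n = 4) for hair shaft keratins, with cashmere higher in 4 of 4 months (exact two-sided sign-flip permutation test: 2 of 16 sign patterns gave a difference as large, the fewest that 4 months allow). It was 2.89 ± 1.63 for keratin-associated proteins, also in 4 of 4 months (2 of 16 sign patterns). For inner root sheath genes it was 1.07 ± 2.47, with cashmere higher in 2 of 4 months (10 of 16 sign patterns). The 6 inner root sheath genes found by product name in the second count table gave 1.37 ± 2.48. There cashmere was higher in 3 of 4 months (6 of 16 sign patterns). None of these could reach a p of 0.05 in this exact test. With counts scaled by TMM, chosen after the data were seen, shaft keratins were lower in cashmere goats at month 9 (-0.23), so that cashmere was higher in 3 of 4 months (4 of 16 sign patterns). Keratin-associated proteins stayed higher in 4 of 4 months under that scaling (2 of 16 sign patterns). The intervals of the shares cover counting error only. Reads may also be shared between near-identical keratin and keratin-associated protein copies.

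**Figure D2:**
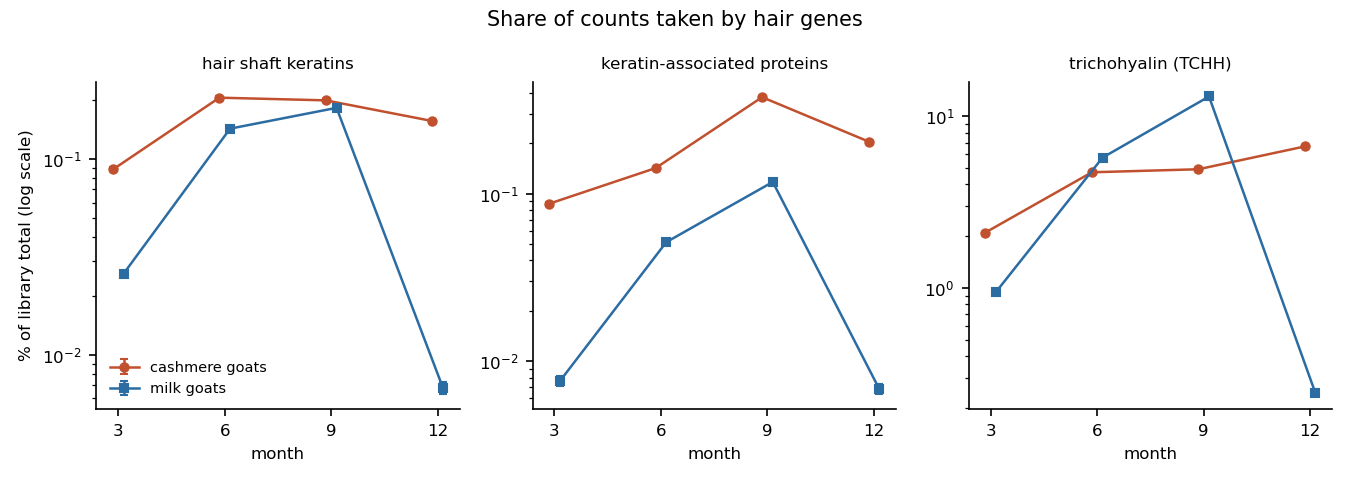
Percent of each library's reads (log axis) taken by 8 hair shaft keratins, 4 keratin-associated proteins and TCHH, by month, with circles for cashmere and squares for milk goats; bars are 95% exact binomial intervals. The milk goat share of hair shaft keratins is 0.183% at month 9 and 0.00675% at month 12, while the cashmere goat share is 0.200% and 0.157%.

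Within single months the breeds were compared as 1 library against 1, without a test. At month 12 TCHHL1, a trichohyalin relative, had the highest log2 ratio, at 5.91, with KRTAP15-1 at 5.56 and KRT26, an inner root sheath keratin, at 5.44. LCN2, the secreted lipocalin of innate defence, had 162 reads against 3 (5.54, exact interval 4.76 to 8.63), and LYG2, a lysozyme-like gene, had a ratio of 5.05. Among the lowest ratios were those of CHGB, a granule protein of neuroendocrine cells (1 read against 132, exact interval -11.8 to -3.96), DNAH17 (-3.90), NEFH (-3.89) and PTH1R, the parathyroid hormone receptor (-3.79). Hair shaft keratins had a median log2 ratio of 4.37, inner root sheath genes of 4.49, keratin-associated proteins of 4.95, matrix regulators of 2.29 and cell division genes of 1.40 at this month. Each of these 5 medians lay above all 10000 random lists of like size and expression. Endothelial genes stood at -1.0 with 18 of 18 lower, ribosomal proteins at -0.53 and skeletal muscle genes at -1.15 in the same pair of libraries.

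At month 3, GREB1, an oestrogen-induced gene, had the highest ratio (4.00), followed by CHAC1, a glutathione-degrading enzyme (3.86), KRTAP3-1 (3.76), KRTAP11-1 (3.48) and the hair keratin KRT39 (3.2). SFRP4, a secreted Wnt modulator (-4.07), KERA, a matrix proteoglycan (-3.76), TNNT2 (-3.11), the interferon-induced chemokine CXCL9 (-3.06) and ANGPTL1 (-2.36) had the lowest. At month 6, S100A7A, an antimicrobial S100 protein, stood highest (4.82), before the melanocyte channel TRPM1 (3.55), KRT38 (3.49), KRT4 (2.74) and CA4 (2.58). SCN9A (-2.62), HMGN5 (-2.04), CD300E (-1.88), PPIG (-1.87) and ARHGAP22 (-1.86) stood lowest. At month 9, S100A7A had 184 reads against 0 (exact lower limit of the log2 ratio 5.94). KRT4 (3.57), the imprinted gene NNAT (3.53), CDO1, a cysteine dioxygenase (3.30), and KAP8 (2.61) followed, and HMGN5 (-3.52), TNNT2 (-2.94), PTH1R (-2.89), NEXN (-2.81) and the shaft keratin KRT38 (-2.79) were lowest. Hair shaft keratins had median log2 ratios of 1.88, 0.54 and -0.29 at months 3, 6 and 9, and the last was 0.11 for the 17 shaft keratins found by product name in the second count table. Keratin-associated proteins stood at 2.80, 1.53 and 1.53 in these months. Inner root sheath genes stood at 1.36, 0.31 and 0.09, with -0.92 at month 9 in the second table. Macrophage genes stood at -0.61, -0.64, 0.81 and -0.62 at months 3, 6, 9 and 12. More than 2-fold ratios were seen for 980, 737, 1599 and 2893 of 14085 genes at months 3, 6, 9 and 12.

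**Figure D3:**
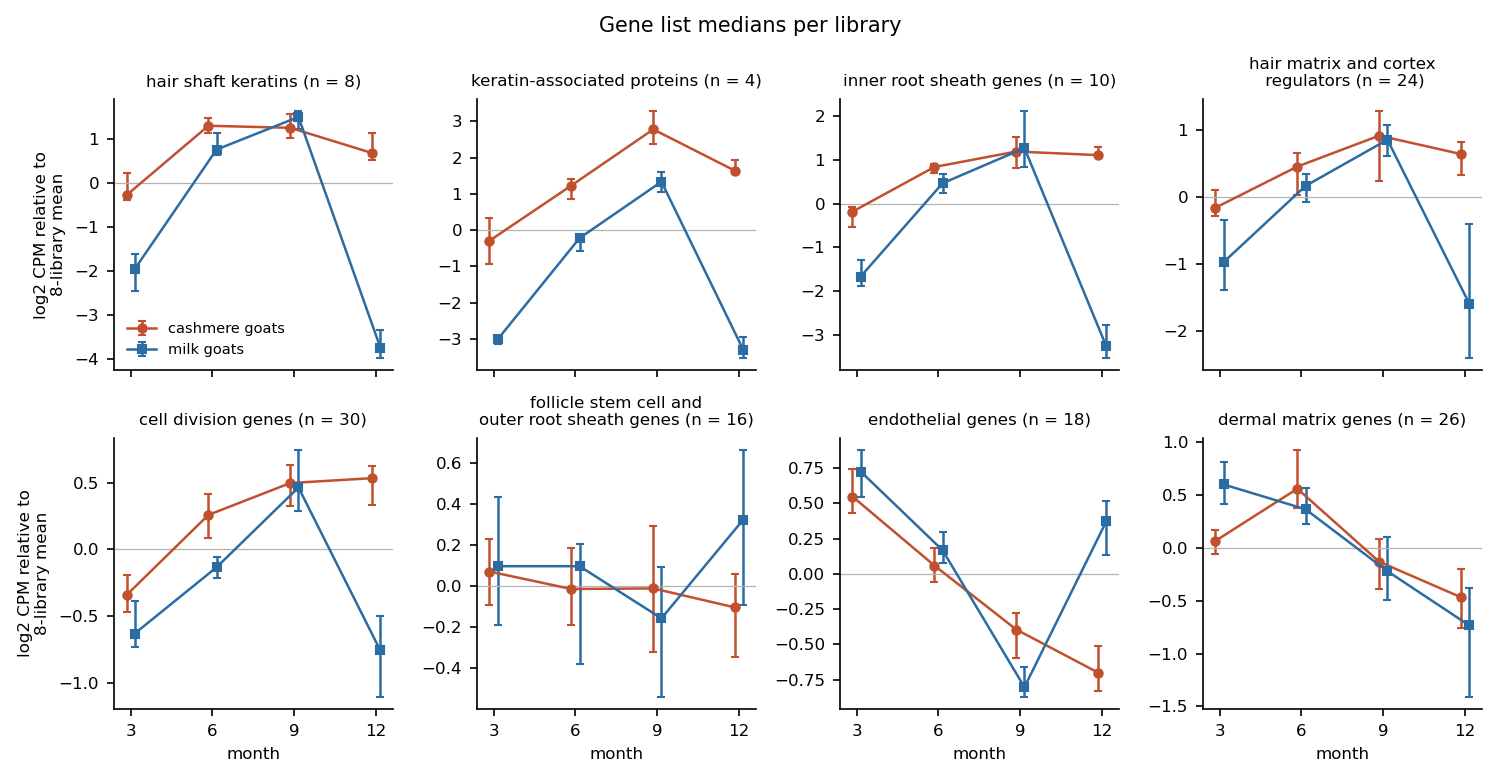
Median log2 CPM of 8 gene lists in each library relative to the mean of the 8 libraries, by month, with circles for cashmere goats, squares for milk goats and bars for the quartiles over the genes of the list. Hair shaft keratins reach -3.75 in milk goats at month 12 and 0.67 in cashmere goats at that month, while endothelial genes stand at 0.37 and -0.70.

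Month 9 was set against month 3, with 2 libraries each. If months of the year are meant, these lie on opposite sides of a 12-month cycle. Hair genes and cell division genes were higher and blood vessel genes lower at month 9, as lists, while 0 genes passed over all genes with edgeR. At an unadjusted p under 0.05 there were 3329 genes (704 by chance), and the smallest adjusted p was 0.108. DESeq2 called 1107, limma on log2(FPKM + 1) 35 and limma on log2(FPKM + 0.1) 0. Hair shaft keratins had a median log2 fold change of 2.45 with 8 of 8 positive (adjusted p = 0.000716), inner root sheath genes 2.49 with 10 of 10 (adjusted p = 0.00185) and matrix regulators 1.47 with 23 of 24 (adjusted p = 2.76e-07). Cell division genes stood at 1.11 with 30 of 30 positive (adjusted p = 2.28e-10) and oxidative phosphorylation genes at 0.49 with 58 of 62 (adjusted p = 9.23e-10). Endothelial genes stood at -1.21 with 18 of 18 negative (adjusted p = 2.28e-10) and dermal matrix genes at -0.65 with 24 of 26 (adjusted p = 0.000246). Each of these 7 lists had adjusted p = 0.446 with an estimated correlation. Adjusted over the list alone, 16 endothelial genes were lower, 16 cell division, 11 matrix regulator and 5 shaft keratin genes were higher, and 1 dermal matrix gene was higher and 4 lower. Among oxidative phosphorylation and inner root sheath genes 0 passed when adjusted over the list alone.

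Another 9 of the 29 lists were called between months 9 and 3. Cholesterol synthesis (median 0.45, adjusted p = 0.000386), immediate early (0.47, adjusted p = 0.00461), heat shock (0.38, adjusted p = 0.0112) and epidermal differentiation genes (0.29, adjusted p = 0.0299) were higher at month 9. Circadian clock (-0.59, adjusted p = 0.00419), Schwann cell and nerve (-0.62, adjusted p = 0.00461), photoperiod hormone receptor (-0.50, adjusted p = 0.0129), T and NK cell (-0.82, adjusted p = 0.0222) and smooth muscle genes (-0.62, adjusted p = 0.0299) were lower. T and NK cell genes had adjusted p = 0.525 and the other 8 lists adjusted p = 0.446 with an estimated correlation. Adjusted over the list alone, 8 Schwann cell and nerve genes were lower and 1 higher, 4 photoperiod genes were lower and 1 higher, 6 smooth muscle genes were lower and 2 higher, 4 epidermal genes were higher and 1 clock gene was higher, with 0 among cholesterol synthesis, immediate early, heat shock and T and NK cell genes. With library totals the median of all genes was -0.32, and that of epidermal differentiation genes turned to -0.04. The difference in T and NK cell genes lay in milk goats, where the median at month 3 over month 9 was 1.21 with 11 of 13 positive, against 0.13 with 7 of 13 in cashmere goats (single libraries, no test). Their mean of -0.71 went to -0.02 without the milk goat library of month 9.

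Other list means of this contrast also moved when 1 library was left out. The values that follow are means over a list, so they are not to be compared in size with the medians given above for all libraries. The highest value came without the cashmere goat library of month 9 and the lowest without the milk goat library of that month for hair shaft keratins (4.25 and 1.34), inner root sheath genes (3.17 and 1.17), matrix regulators (1.87 and 0.77), cell division genes (1.36 and 0.59) and heat shock genes (0.59 and 0.14). Under the same 2 settings clock genes stood at -0.66 and -0.23, and smooth muscle genes at -0.12 and -0.37. Dermal matrix genes stood at -0.89 without the cashmere goat library of month 3 and -0.13 without the milk goat library of that month. Immediate early genes stood at 0.23 and 0.59 under those 2 settings, and epidermal differentiation genes at 0.60 without the cashmere goat library of month 3 and 0.22 without the milk goat library of month 9.

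Without both month 12 libraries, an alternative chosen after the data were seen, the same contrast called 2028 genes in 6 libraries. Of these, 1119 were higher and 909 lower at month 9. All had the same direction in both breeds, which is no separate support, since opposite directions would leave a large residual. The fit of these 6 libraries had 2 residual degrees of freedom. Leaving out only 1 of the month 12 libraries is no separate check, since the other one then adds no residual. KRTAP15-1 was higher by 4.50 ± 0.19 on the log2 scale (22.7-fold, adjusted p = 0.000584), KAP8 by 4.35 ± 0.26 (20.4-fold, adjusted p = 0.00361) and TCHHL1 by 4.25 ± 0.39 (19.0-fold, adjusted p = 0.0113). LCN2 was higher by 4.80 ± 0.42 (adjusted p = 0.0113). KRT38 was higher by 7.33 ± 1.83 (adjusted p = 0.0413), with 3.88 in cashmere goats and 9.0 in milk goats. Its size rests on a milk goat level of 0.163 CPM at month 3, below the 0.244 CPM that 3 reads stand for in that library. The granule protein gene CHGA (-3.94 ± 0.40) and FOXI3, a transcription factor of hair placodes (-2.96 ± 0.33), were lower, each at adjusted p = 0.0113. SLC1A2, a glutamate transporter (-2.33 ± 0.45, adjusted p = 0.0227), and SCN9A (-2.31 ± 0.41, adjusted p = 0.0186) were lower too.

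In these 6 libraries 7 of 8 hair shaft keratins, 4 of 4 keratin-associated proteins, 7 of 10 inner root sheath genes, 15 of 24 matrix regulators and 19 of 30 cell division genes rose. MSX1, a homeobox gene of the matrix, rose by 2.01, VDR, the vitamin D receptor, by 1.36 and TOP2A, a topoisomerase of dividing cells, by 1.58. Of 18 endothelial genes 15 fell, among them the receptor KDR (-1.50 ± 0.16, adjusted p = 0.0113), the adhesion molecule PECAM1 (-1.46), the receptor TIE1 (-1.44) and the tight junction gene CLDN5 (-1.72). Schwann cell and nerve genes showed 7 lower and 1 higher, with the neurotrophin receptor NGFR at -1.57 and the transcription factor SOX10 at -1.37. In the photoperiod list the oestrogen receptor ESR1 (-1.69 ± 0.33, adjusted p = 0.0237) fell. In the same list DIO2, which activates thyroid hormone (0.75 ± 0.15, adjusted p = 0.0234), and DIO3, which inactivates it (2.16 ± 0.43, adjusted p = 0.0241), rose. Immediate early genes moved with these lists, with 9 of 25 higher, among them JUNB (1.17) and EGR1 (1.02).

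**Figure D4:**
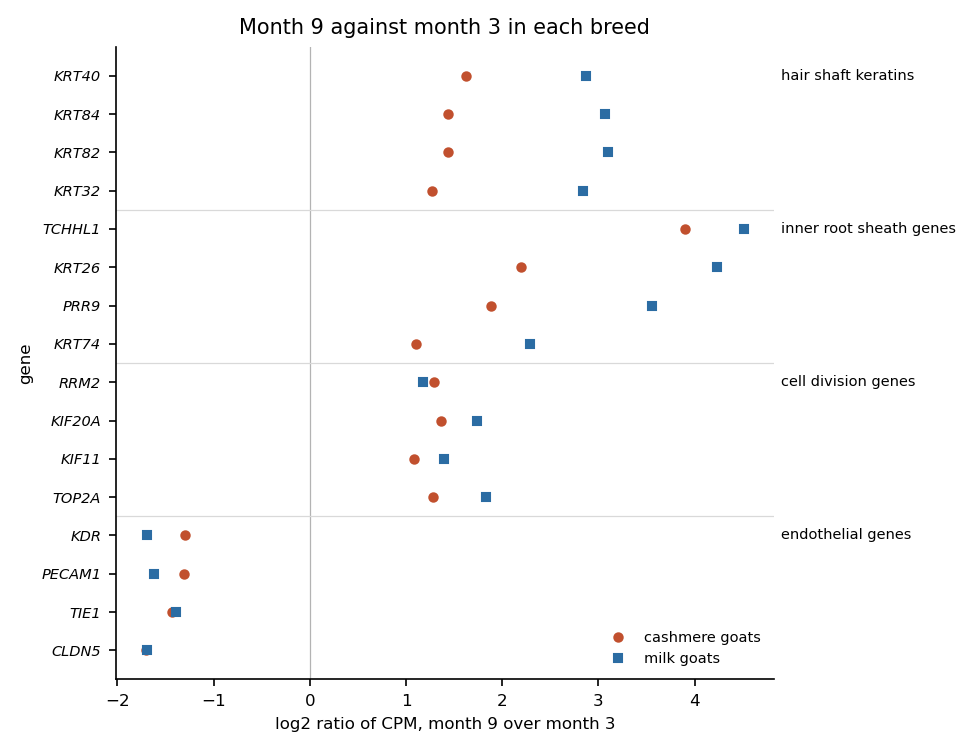
Log2 ratio of CPM at month 9 over month 3 within cashmere goats (circles) and within milk goats (squares), 1 library per point, for 4 genes of each of 4 lists; the genes are the members with the smallest p in the comparison without month 12. KDR lies at -1.30 in cashmere and -1.69 in milk goats, and TCHHL1 at 3.90 and 4.51.

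Month 12 was set against month 6, the other opposite pair of such a cycle if months of the year are meant. Genes of the dermal matrix were lower at month 12 as a list, with a median log2 fold change of -0.97 and 26 of 26 negative (adjusted p = 3.06e-20; adjusted p = 0.383 with an estimated correlation). Adjusted over the list alone, 16 of the 26 were lower. The values were -4.26 ± 0.82 for the fibrillar collagen gene COL1A1 (adjusted p = 0.405 over all genes) and -4.05 for COL1A2 (adjusted p = 0.360). COL1A1 had 17749 CPM in cashmere goats at month 6 and 735 at month 12, against 6076 and 539 in milk goats. Dermal papilla genes had a median of -0.40 with 17 of 21 negative (adjusted p = 0.000123; adjusted p = 0.383 with an estimated correlation), and 2 were lower when adjusted over the list alone. This was the only list that fry called as moving one way (adjusted p = 0.0321). For the breed effect, for month 9 against month 3 and on each season axis, fry called 0 of 29 lists. Wnt and BMP inhibitors and ligands stood at -0.38 (adjusted p = 0.00433; adjusted p = 0.383 with an estimated correlation), with 1 higher when adjusted over the list alone.

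Hair shaft keratins (-2.01, 8 of 8 negative, adjusted p = 5.53e-06), matrix regulators (-0.58, adjusted p = 0.00173), inner root sheath genes (-1.0, adjusted p = 0.00433) and macrophage genes (-0.64, adjusted p = 0.00284) were lower at month 12, each with adjusted p = 0.731 with an estimated correlation. Sebaceous lipid (0.37, adjusted p = 0.00284), skeletal muscle (0.52, adjusted p = 0.0112), oxidative phosphorylation (0.16, adjusted p = 0.00284) and circadian clock genes (0.25, adjusted p = 0.0286) were higher, each with adjusted p = 0.731 with an estimated correlation. Ribosomal proteins (0.16, adjusted p = 0.00198) and endothelial genes (-0.14, adjusted p = 0.0286) had adjusted p = 0.831 with an estimated correlation. In these 10 lists 0 genes passed when adjusted over the list alone, except 1 higher sebaceous gene. Over all genes 0 passed with edgeR, with 1071 at an unadjusted p under 0.05 and a smallest adjusted p of 0.196, against 94 with DESeq2, 23 with limma on log2(FPKM + 1) and 17 with log2(FPKM + 0.1). Without the cashmere goat library of month 12 edgeR called 452 genes, and without the milk goat library of that month 4. The mean of the endothelial list turned to 0.23 without the cashmere goat library of month 12. Without the milk goat library of that month the means turned to 0.11 for matrix regulators, 0.20 for inner root sheath genes and -0.074 for ribosomal proteins. The mean of hair shaft keratins was -0.98 without the milk goat library of month 12 and -4.50 without the cashmere goat library, against -2.23 with all libraries. Under the same 2 settings oxidative phosphorylation genes stood at 0.01 and 0.30 (0.17 with all), skeletal muscle genes at 0.24 and 1.29 (0.83 with all) and clock genes at 0.08 and 0.35 (0.24 with all). Without the milk goat library of month 6 macrophage genes stood at -0.05 and sebaceous genes at 0.02, and without the cashmere goat library of that month at -0.83 and 0.46, against -0.48 and 0.28 with all libraries.

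The 4 months were also tested together for a course shared by both breeds. With edgeR 0 genes passed, with 1894 at an unadjusted p under 0.05 and a smallest adjusted p of 0.303, against 536 with DESeq2, 18 with limma on log2(FPKM + 1) and 0 with log2(FPKM + 0.1). Without the cashmere goat library of month 12 edgeR called 1180 genes, without the milk goat library of that month 109, and without both 600.

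The last comparison asked whether the course over the months differed between the breeds, as a difference in a 12-month wave. This reads the months as months of the year, which is not settled. PENK, the precursor of enkephalin peptides, had the smallest p, at adjusted p = 0.0735. Its level was 44.7, 19.99, 15.2 and 37.9 CPM in cashmere goats at months 3, 6, 9 and 12 and 6.27, 22.5, 56.3 and 18.8 CPM in milk goats. CHAC1 came next among genes with a symbol (adjusted p = 0.1001), at 107 CPM in cashmere and 4.93 CPM in milk goats at month 12; both genes were chosen after their values were seen. With edgeR 0 genes passed and 904 had an unadjusted p under 0.05, against 79 genes with DESeq2, 2 with limma on log2(FPKM + 1) and 3 with log2(FPKM + 0.1). Without 1 library this model keeps fewer than its 2 residual degrees of freedom, so counts from such runs do not show genes masked by a library. Leaving out any 1 library gave 38 to 501 genes, with 38 without the cashmere goat library of month 12 and 501 without the milk goat library of month 6. The other 6 libraries gave 175, 117 and 88 genes when left out in cashmere goats at months 3, 6 and 9, and 89, 151 and 39 in milk goats at months 3, 9 and 12.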

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

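The list tests on the season coefficients, the test of stem cell genes and the fit without month 12 were chosen after the result was seen. Each coefficient below is the median over a list of the difference between breeds in the height of a 12-month wave (log2), with camera at the preset correlation. With an estimated correlation no list was called, and the smallest adjusted p was 0.774 on the axis of months 12 and 6 and 0.749 on the axis of months 3 and 9. On either axis a positive value means that cashmere goats stood higher, relative to milk goats, at month 12 than at month 6, or at month 3 than at month 9.

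A difference between the breeds drew attention to 8 lists on the axis of months 12 and 6. Inner root sheath genes stood at 1.93 (9 of 10 positive), hair shaft keratins at 1.82 (7 of 8), regulators of the hair matrix and cortex at 0.91 (21 of 24) and cell division genes at 0.45 (28 of 30). Endothelial genes stood at -0.42 (18 of 18 negative), sebaceous lipid genes at -0.35 (20 of 24), ribosomal proteins at -0.20 (73 of 88) and oxidative phosphorylation genes at -0.14 (49 of 62).

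The same kind of difference drew attention to 11 lists on the axis of months 3 and 9. Hair shaft keratins stood at 0.90 (8 of 8 positive), inner root sheath genes at 0.71 (9 of 10), matrix regulators at 0.51 (20 of 24), heat shock genes at 0.29 (14 of 17) and epidermal differentiation genes at 0.22 (18 of 23). Macrophage genes stood at -0.84 (16 of 17 negative), interferon response genes at -0.56 (21 of 22), T and NK cell genes at -0.39 (12 of 13), dermal matrix genes at -0.29 (23 of 26), circadian clock genes at -0.21 (15 of 20) and endothelial genes at -0.19 (15 of 18). In the gene-level test of breed by season the real count was 0, which all 32 splits of the 8 libraries must reach, so the splits decide nothing there. The highest of the other splits called 951 genes. It set months 3 and 12 of cashmere goats with months 6 and 9 of milk goats, and the terms of that model hold the breed difference itself.

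The low hair genes of milk goats at months 12 and 3 were set against technical explanations. Fewer whole follicles in those skin pieces would lower stem cell and outer root sheath genes by about as much as the hair genes. At month 12 against month 9 in milk goats their median was 0.60 (bootstrap interval over 16 genes -0.03 to 1.07) and that of shaft keratins -5.19. At month 3 against month 9 the 16 genes stood at 0.10 and shaft keratins at -3.16. As a list these genes thus did not fall with the hair genes. A loss of follicles stays open, since not all members are confined to follicles and they went both ways. At month 12 KRT6A stood at -2.12, LGR5 at -1.46 and LHX2 at -0.84, against POSTN at 1.04 and COL17A1 at 0.63. At month 3 KRT6A stood at -2.78. Dermal papilla genes stood at -0.52 at month 12 and 0.14 at month 3. A few genes taking most of the counts is argued against by a scaling that left out hair genes and the 10 largest genes, which gave -5.22 (interval -5.64 to -4.64, 8 genes). A swap of the breed labels at month 12 is argued against by a fit without month 12, limited to the genes tested with all libraries. It called 841 genes (843 without that limit), of which 88.3% (interval 86.0 to 90.4) kept their direction at month 12. The values are consistent with a hypothesis of resting follicles in milk goats at months 12 and 3, and the number of animals behind each library, their age and their season of sampling stay open and untested. Sections of the same skin pieces, with follicles counted by phase, would decide it and were not available.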

How the results depend on the processing

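The second count table, the runs without both month 12 or both month 3 libraries, the length, depth and hair score alternatives, library totals, TMM-scaled shares, the ribosomal list without kinases, the other form of the season and the hair classes by product name were chosen after seeing the data. The breed effect (675 genes) stayed within 1.5 times its count with RLE factors (677), a scaling without hair genes (675), no filter (888), a stricter filter (673), library totals (619), a length trend (666), thinned libraries (616), a hair score (723) and without month 12 (843). It gave 1712 genes with DESeq2, 1580 and 1313 with limma on log2 FPKM plus 1 and plus 0.1, 346 without a month term and 1117 with the second table. Shared with the 675 were 668, 532, 515 and 320 genes for the first 4 of these. The month effect (0) gave 536 with DESeq2, 18 with FPKM plus 1 and 600 without both month 12 libraries. Month 9 against month 3 (0) gave 1107, 35 and 2028 under the same settings. Month 12 against month 6 (0) gave 94 with DESeq2 and 23 and 17 with FPKM plus 1 and plus 0.1, and stayed at 0 with edgeR without month 3 (826 at an unadjusted p under 0.05). Breed by season (0) gave 79 with DESeq2, 118 with no filter, 2 and 3 with FPKM plus 1 and plus 0.1 and 2 with months 12 and 3 set against 6 and 9. With the second table these last 4 comparisons gave 0 genes with edgeR (1806, 3073, 1272 and 844 at an unadjusted p under 0.05). The list calls (7, 16 and 13, and 8 and 11 for the season axes) all went to 0 with an estimated correlation. Without 9 S6 kinases and RPS19BP1 in the ribosomal list the 5 counts of called lists stayed the same. At month 9 the median breed ratio of hair shaft keratins turned from -0.29 to 0.11 and that of inner root sheath genes from 0.09 to -0.92. This was with classes by product name in the second count table, so that table and classes changed together. Leaving out 1 library gave 0 to 869 genes for the breed effect, 0 to 1180 for the month effect, 0 to 2027 for month 9 against month 3, 0 to 452 for month 12 against month 6 and 38 to 501 for breed by season. It gave 1 to 11 lists for the breed effect, 11 to 19 for month 9 against month 3 and 8 to 13 for month 12 against month 6. In month 12 against month 6 the list mean ran over the runs that leave out 1 library from -0.79 to 0.23 for endothelial genes (highest without cashmere month 12), -1.64 to 0.11 for matrix regulators, -3.28 to 0.20 for inner root sheath genes (both highest without milk month 12) and -0.074 to 0.41 for ribosomal proteins (lowest without milk month 12). The cause was not tested for any of these changes. A month with 1 library left is assumed to vary like the others and adds no residual. The 20 named breed genes kept their sign in 419 of 419 values over 21 alternatives and lost the call in 140. The kept sign is no separate support, since these genes were chosen for a large fold change with the same sign in all 4 months. Depth limits genes under 0.395 CPM, the level of 3 reads in the smallest library after scaling.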

Other observations

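The lists of HOX genes and splicing factors, the test of HOX genes against matched lists, the hair classes by product name, the length trend, the thinned libraries, the hair score and the scaling by library totals were chosen after the result was seen. HOX genes, which pattern the body axis and stay active in adult skin fibroblasts, were mostly lower in cashmere goats, with 20 of 25 negative and a median log2 fold change of -0.64 (camera p = 1.71e-05 at the preset correlation and p = 0.245 with an estimated correlation, neither adjusted). Of these, 6 fell past the threshold over all genes: HOXB7 (-1.52, adjusted p = 0.0170), HOXC9 (-1.70, adjusted p = 0.0218), HOXB6 (-0.98), HOXC4 (-1.25), HOXC6 (-0.69) and HOXC8 (-1.16). HOXC13, which drives hair keratin genes, stood at 1.74 (adjusted p = 0.0706). Of 93 genes of splicing factor families, 64 were negative with a median of -0.14, 7 fell and 1 rose (camera p = 0.00220, and p = 0.273 with an estimated correlation).

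Pigment and surface lipid genes also differed by breed in single members. In the melanocyte list 7 genes were higher and 1 lower when adjusted over the list alone, with a median of 1.02 (adjusted p = 0.206 for the list). Their levels were low, as for MLANA (1.73 CPM on average, 1.75 on the log2 scale) and PMEL (1.34 CPM, 1.18). Among cholesterol synthesis genes MSMO1 (0.78, adjusted p = 0.0276), TM7SF2 (0.93, adjusted p = 0.0429) and INSIG1 (0.78, adjusted p = 0.0429) rose. In the second count table hair shaft keratins found by product name (17 genes) took 2.35% of reads in cashmere and 0.0875% in milk goats at month 12, and 3.40% and 2.27% at month 9. Keratin-associated proteins found in the same way (29 genes) took 1.006% and 0.0412% at month 12.

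More genes were called lower (468) than higher (207) in cashmere goats. Of 32 splits that part the libraries 4 against 4, 1 split, the real one, gave as many as 675 genes, and the highest other gave 60. Only 8 of them part all 4 months as the breeds do, and among these the highest other gave 1 gene, but 8 splits are too few for a share under 0.05. The others part 2 months only, so they are not like the real one. In every split but the real one at least part of the breed difference goes into the residual, which lowers the count. The splits were also counted without direction, so they do not test the skew. A difference in depth is argued against as the cause of the skew, since thinned libraries gave 74.3% lower (range 70.3 to 75.6 over 10 draws), and a length trend likewise, with 69.7% (interval 66.0 to 73.1). More hair-forming cells in cashmere skin stays open. Genes lower in cashmere had a median log2 ratio of 0.25 (interval 0.19 to 0.32) at month 12, poor in hair transcripts, over month 9 in milk goats, and genes higher in cashmere of -0.41, against 0.05 for all genes. In cashmere goats the same ratios were 0.17 and -0.29, against -0.03 for all genes. Shaft keratins there went from 0.200% of reads at month 9 to 0.157% at month 12, and keratin-associated proteins from 0.377% to 0.205%. TCHH rose from 4.89% to 6.64% between these cashmere goat libraries. Much of the size of the ratios thus appears without a loss of hair transcripts like that in milk goats. With a hair score as a covariate 723 genes were called, 440 of them shared, and 56.8% were lower (interval 53.1 to 60.5). The limit of 0.5 set beforehand for that ratio excludes nothing here, since it rests on 1 library of each month. The scaling may account for the skew, since library totals gave 51.2% lower (interval 47.2 to 55.2), and which scaling is right stays open.

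The number of lists called between the breeds gave another picture, since 24 of the 32 splits called at least as many lists as the real 7, with up to 15, so chance cannot be excluded there.

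The lower HOX genes were set against technical explanations. Matched random lists of genes of like level and length had medians of -0.17 to 0.25, so such genes in general did not share the median of -0.64. That the HOX genes lay below these lists is no separate support for a difference. The HOX list was chosen after its values were seen, and the random lists were drawn gene by gene, while HOX genes may move together. A few libraries may decide the size of the difference: the median was -0.26 without the cashmere goat library of month 12 and -0.28 without the milk goat library, against -0.75 to -0.68 without the others. Another body site sampled in 1 breed cannot be told apart from a breed difference, since the labels give no site and the rank correlation between position in the cluster and fold change was -0.12 across genes, which are not independent replicates.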
